A study of Drosophila melanogaster with 12 samples.

How the data were processed

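RNA from adult heads of cn bw flies, a strain named for the eye colour mutations cinnabar and brown, was measured on 12 Affymetrix arrays. Per the labels, flies had been entrained to a cycle of 12 hours of light and 12 hours of dark and were collected every 4 hours through 1 more such day (Zeitgeber times ZT4 to ZT24, counted from lights on) and then through 1 day of constant darkness (circadian times CT4 to CT24). Per the labels' protocols, flies were frozen on dry ice, about 100 to 200 heads were isolated on sieves, RNA was taken with 1 of 2 phenol reagents and cleaned on columns, and about 25 µg was turned into biotin-labelled cRNA. Which reagent served which array is not given in the sources used here.

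The deposited values are 1 number per probe set and array, made by the authors with RMA, per the submitters' processing notes, which state no version. RMA corrects background, normalizes arrays to each other and summarises the probes of a set. The unit was taken as log2, because the deposited values ran from 1.72 to 13.52 in all 12 columns, the range that RMA gives on that scale; the log base is inferred, not stated. Array medians lay between 4.81 and 4.88, but the columns did not share 1 distribution, so between-array normalization was less complete than a full quantile step over these 12 columns would give. A ratio from RMA values understates changes of weakly expressed genes. The file held 14010 probe sets. The 44 control probe sets were set aside for checks of array quality, and 13966 were tested. No column of per-sample values was left unused. Arrays give no read depth, and their number limits the precision: the median standard error of the difference between the days was 0.09 on the log2 scale.

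Names came from the platform annotation supplied with the values, updated through gene identifiers in a RefSeq gene table of the fly assembly Release 6 plus ISO1 MT, used for names only. Of the tested probe sets, 12443 had 1 gene, 327 had several and 1196 had none here; 12394 names were found in the newer table. Probe sets with several genes or none were tested but not named. No coordinates are given, since the array's genome build is not given in the sources used here. A gene was represented by its probe set with the highest mean over the 12 arrays, which gave 10844 genes; 1209 of them had more than 1 probe set.

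All tests were run with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment over all 13966 tested probe sets, at a threshold of adjusted p = 0.05. The daily rhythm was fitted as a cosine and a sine with a period of 24 hours beside a step between the days, and both terms were tested together. A second model held a separate cosine and sine for each day; it gave the rhythm within each day and the difference of the rhythm between the days. Amplitude is the fitted peak minus the fitted mean on the log2 scale, and its error is a standard error (SE). The size of a difference of rhythm is the length of the vector of the differences in cosine and sine terms. Mean levels of the days were compared in the model with the common rhythm. With 1 array per time point, the spread was taken from the residuals around the fitted curves of all 12 arrays.

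Of 28 gene lists, those for the rhythm were tested by Fisher's exact test, 1-sided for more called genes, and those for the mean level by limma's camera, 2-sided, with a preset correlation of 0.01, and also with an estimated correlation and with fry. Each was adjusted over the 28 lists. The lists were the core clock, clock kinases and modifiers, earlier reported head oscillators, phototransduction and photoreceptor genes, eye pigment and pteridine genes, activity-regulated genes, cytochrome P450, glutathione S-transferase, UDP-glycosyltransferase, immune effectors, heat shock and stress, feeding and lipid metabolism, neuropeptides and receptors, ion channels, ribosomal proteins, proteasome, oxidative phosphorylation, odorant-binding proteins, odorant and gustatory receptors, cuticle proteins, and markers of neurons, glia, head fat body, muscle, haemocytes, gut, testis and accessory gland, and ovary. The photoreceptor list also served as a marker list. Head oscillators were recalled from published time courses that could include related arrays, so that list is not independent evidence. The lists, tests and alternatives were written before the data were examined, with these exceptions: name patterns were corrected afterwards so that cyclophilins left the cytochrome P450 list, Prosap left the proteasome list and 3 genes outside the odorant-binding family left that list, and 1 mistaken symbol was taken out of the eye pigment list.

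Genes were named by a rule fixed in advance: all core clock genes; rhythmic genes past the threshold with similar peaks in both days, up to 16; for the difference of rhythm, the genes past the threshold and then the 6 with the smallest p as values; for the mean level, up to 12 genes past the threshold per direction or else the 5 with the smallest p as values; up to 4 members per list; and cn and bw. Other genes named were chosen after their values were seen, and are marked as such.

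RNA quality was followed through the array's fly control genes (actin, eIF4A and GAPDH), as the log2 signal of the 3' probe sets minus that of the 5' probe sets, since labelling starts at the 3' end; through bacterial spike-in controls; and through marker lists, as the median over genes of each array's value minus the gene's mean. The procedure was tested on simulated data. A rhythm, a change of mean level and a difference of rhythm were each added to 200 separate genes, all at once on top of the deposited values. The rhythm test called 75 of 100 genes with an amplitude of 0.5 and 97 of 100 with an amplitude of 1. The test of the mean level called 91 of 100 genes at a log2 change of 1, and the test of the difference called 73 of 100 genes at a size of 1. Among probe sets without an added change, the tests of rhythm, mean level and difference called 2, 1 and 15. With so many truly changed genes the adjustment is milder than for a few, so these shares are upper estimates.

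Alternatives fixed in advance were a filter on weak probe sets, quantile normalization again, centring, an added constant on the linear scale, another variance prior, counting probe sets, other terms for the rhythm, the hour or the slow change, each day alone, and each array left out in turn. Added after seeing the data were covariates for RNA quality and principal components, array weights, a squared term for time, and fits without 4 arrays of doubtful quality (ZT16, ZT24, CT4 and CT8). Those fits without 4 arrays keep ZT4, ZT8, ZT12 and ZT20 of 1 day and CT12, CT16, CT20 and CT24 of the other. Their days no longer hold the same hours, so the day and rhythm terms are partly confounded.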

Results

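Adult heads of cn bw flies were followed through 1 light/dark day (6 arrays, ZT4 to ZT24) and the next day in constant darkness (6 arrays, CT4 to CT24), sampled every 4 hours. The study asked, by its design, which head transcripts follow a daily rhythm and whether the rhythm runs on without light. There was 1 array per time point and no replicate at any time point, and the labels do not say whether time points came from separate collections of flies, so p-values measure the spread of arrays around the fitted curves. Constant darkness was also the later day, so lighting, elapsed time and any batch cannot be told apart.

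The genes that give the strain its name were steady. The ommochrome pathway gene cn measured 4.70 ± 0.08 (SD, n = 6) in the light/dark day and 4.69 ± 0.12 in constant darkness, and the pigment transporter gene bw 6.06 ± 0.18 and 6.09 ± 0.09, all log2. A second probe set of bw was weaker, at a mean of 3.34. The level of cn lay at percentile 46 of the probe sets, so its steadiness may be partly that of background. The arrays differed in RNA quality. The 3' minus 5' signal of the control genes was 3.32 in ZT24, 2.88 in CT4 and 2.58 in ZT16, against 1.49 to 2.13 in the other arrays. Muscle markers, among them the myosin light chains Mlc1 and Mlc2, had list medians of -0.33 in ZT16, -0.31 in ZT12 and -0.29 in CT4 relative to each gene's mean. In CT8, digestive enzyme and lysozyme genes of the gut stood high and neuronal genes low: the gut list's median was 0.28 and the neuron list's -0.49. The lysozyme gene LysD was at 8.36 in CT8, against 7.10 ± 0.09 (SD, n = 11) in the other arrays, LysS at 8.29 against 8.74 ± 0.24, and the synaptic vesicle gene Syn at 2.59 against 4.19 ± 0.32.

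**Figure D1:**
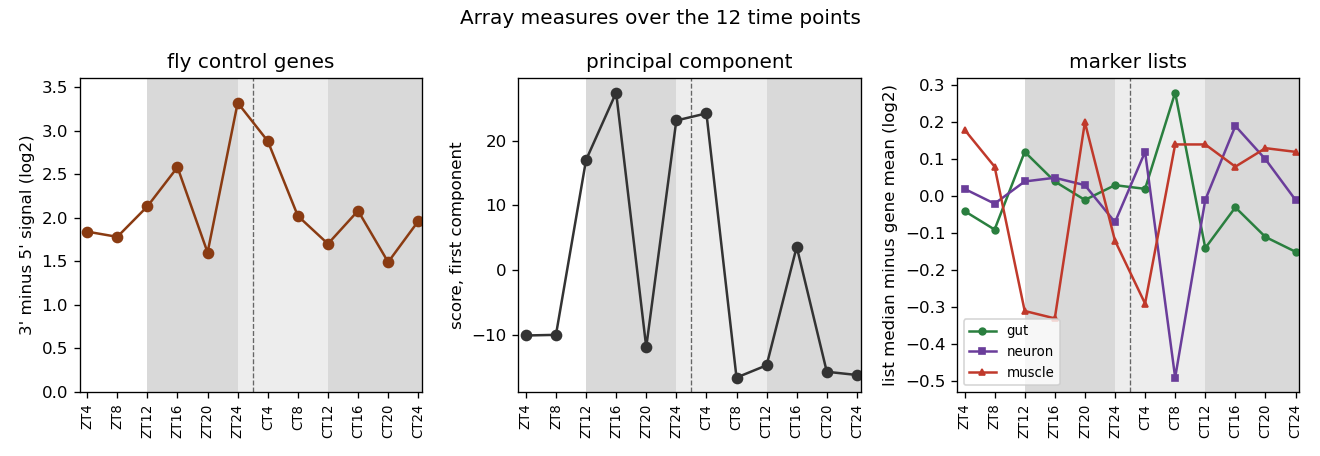
Array measures at the 12 time points, 1 point per array: the log2 3' minus 5' signal of the fly control genes (left), the score on the first principal component (middle), and the median over gut, neuron and muscle marker genes of the log2 value minus the gene's mean (right). Grey marks darkness and light grey the subjective day, and the dashed line separates the light/dark from the constant darkness arrays. The 3' minus 5' signal reached 3.32 in ZT24, and the neuron list had a median of -0.49 in CT8.

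Across both days, the clearest daily rhythm was that of vri, which encodes a transcription factor that represses Clk in the second loop of the fly clock. Its transcript rose from 5.43 at ZT4 to 6.79 at ZT16 and from 5.32 at CT4 to 6.66 at CT12. The fitted amplitude was 0.71 ± 0.07 (SE, n = 12), a 2.68-fold change from trough to peak, with a peak at 13.8 ± 0.4 hours, in the early night (adjusted p = 0.0403). The clock gene tim, whose protein pairs with PER and is broken down in light, had an amplitude of 0.81 ± 0.14 and a peak at 16.1 hours. It missed the threshold over all genes (unadjusted p = 3.394e-04 by limma, n = 12) and passed when adjusted over the list alone (adjusted p = 0.0014). A second probe set of tim gave 0.53 ± 0.10 with a peak at 16.4 hours, and another, near the floor at a mean of 2.06, gave 0.04 ± 0.04.

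The other core clock genes had smaller fitted amplitudes, none of which passed. The repressor gene per measured 0.20 ± 0.10 with a peak at 14.9 hours, and Pdp1, which encodes an activator of Clk, 0.30 ± 0.15 with a peak at 16.6 hours. Clk, which encodes the activator that drives per and tim, measured 0.15 ± 0.06 with a peak at 1.5 ± 1.5 hours (SE). The values were 0.08 ± 0.08 for the repressor gene cwo, 0.07 ± 0.17 for the blue-light receptor gene cry, which was lowest in CT4, ZT16 and ZT24, the arrays with a large 3' minus 5' signal (6.63, 6.74 and 6.82), and 0.06 ± 0.05 for cyc, which encodes the partner of CLK. Of the 8 core clock genes, 1 passed over all genes and 2 adjusted over the list alone. The list's share of called genes exceeded that of other genes by Fisher's exact test (adjusted p = 0.0207), which rests on vri alone. The list's mean -log10 p was also set against 100 orders of the hours within each day, the real order among them. Its permutation p was 0.01, the smallest that 100 orders can give. Adjusted over the 28 lists, this permutation p was 0.28. With so few orders 1 list alone could not go lower, so the adjusted value cannot decide.

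**Figure D2:**
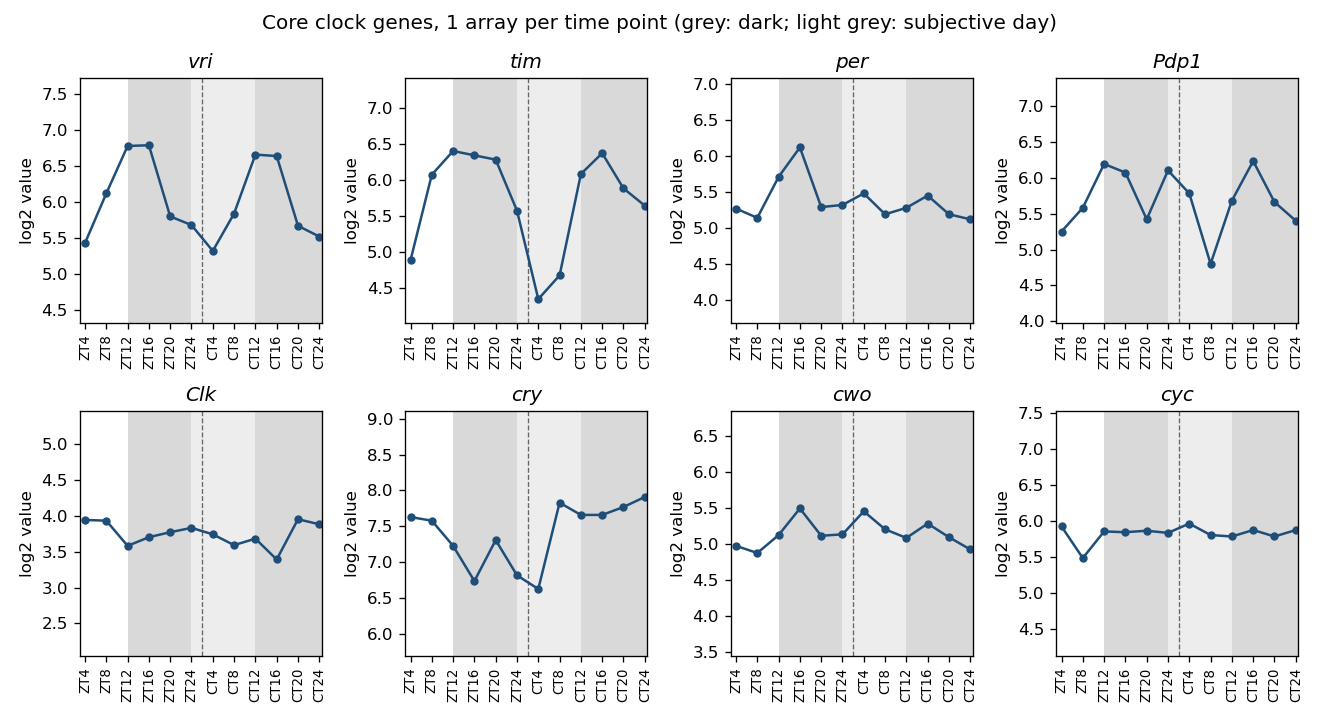
Log2 values of the 8 core clock genes at the 12 time points, 1 point per array, over axes that span the same log2 range. Grey marks darkness and light grey the subjective day, and the dashed line separates the light/dark from the constant darkness arrays. The gene vri peaks at ZT16 with 6.79 and at CT12 with 6.66, while cyc stays between 5.48 and 5.96.

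Over all 10844 genes, limma called 1 gene rhythmic (vri), and 173 genes had an unadjusted p under 0.05, against 542 by chance. An amplitude of at least 0.5 with an unadjusted p under 0.05 was seen in 13 genes. The vri call was lost when any of 10 arrays was left out: adjusted p was 0.2857 without ZT4, 0.1366 without ZT8, 0.3375 without ZT12, 0.2542 without ZT16, 0.0532 without ZT24, 0.1988 without CT4, 0.0697 without CT8, 0.1529 without CT12, 0.2774 without CT16 and 0.0609 without CT24. The amplitude of vri stayed between 0.69 and 0.76 in all 12 of these fits.

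Outside the core clock, members of 2 lists passed when adjusted over the list alone. These values were not adjusted over the 27 lists searched, so such passes can arise by chance, and the head oscillator list is not independent evidence. Cyp6a21, a cytochrome P450 gene among the earlier reported head oscillators, had an amplitude of 0.38 ± 0.07 and a peak at 23.8 hours (adjusted over the list alone, adjusted p = 0.0170). In the wider cytochrome P450 list it did not pass (adjusted p = 0.0723). Cpr72Ec, a cuticle protein gene, had an amplitude of 0.38 ± 0.07 and a peak at 5.5 hours (adjusted over the list alone, adjusted p = 0.0446). Other head oscillators did not pass: the photoreceptor retinol dehydrogenase gene Pdh measured 0.43 ± 0.10 with a peak at 3.1 hours, the glycosyltransferase gene Ugt35B1 0.58 ± 0.17 at 5.0 hours, and CG10513 0.38 ± 0.12 at 2.7 hours. Among the clock kinases and modifiers, the deubiquitinase gene Usp8 measured 0.41 ± 0.13 at 12.8 hours, and among the odorant-binding proteins Obp99a, which is also a fat body marker, 0.53 ± 0.15 at 20.2 hours. In the 27 lists besides the core clock, 0 genes passed over all genes in limma, and 25 of them had 0 genes adjusted over the list alone. With 0 called members, Fisher's exact test could not find any of the 27, and permutation of the hours gave them adjusted p between 0.70 and 1.

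Within each day alone, no gene passed. In the light/dark day, 379 genes had an unadjusted p under 0.05 in limma (smallest adjusted p = 0.7496), and in constant darkness 172 (smallest adjusted p = 0.0970). By chance 542 would be counted in each day. The amplitude of vri was 0.71 with a peak at 13.7 hours in the light/dark day and 0.71 with a peak at 13.9 hours in constant darkness. Its component along the common phase in constant darkness was 1.0 ± 0.22 times that in the light/dark day (SE, 1 gene). The gene vri had been picked by a fit of 1 common rhythm to both days of these arrays, which favours a ratio near 1. For tim, the amplitude was 0.69 at 15 hours in light/dark and 0.98 at 16.9 hours in darkness (difference 0.50 ± 0.25, adjusted p = 0.9861). For per, it was 0.38 at 15.3 hours and 0.05 at 11.4 hours (difference 0.36 ± 0.18, adjusted p = 0.9861), so neither gene's rhythm was shown to differ between the days.

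The shape of the daily curve differed between the days for 1 gene, CASK, which encodes a scaffold protein of synapses. It measured 7.07, 7.17 and 7.0 at ZT4, ZT8 and ZT12, went down to 6.04 at ZT20 and 5.60 at CT8, and was back at 7.33, 7.45 and 6.97 at CT16, CT20 and CT24. Its fitted peak lay at 8.1 hours with an amplitude of 0.62 in the light/dark day and at 19.8 hours with an amplitude of 0.94 in constant darkness. The size of the difference was 1.56 ± 0.12 (SE, n = 12; adjusted p = 0.0255). The genes next in p did not pass: Edc3, an mRNA decapping factor, with a size of 2.58 ± 0.25 (adjusted p = 0.0535); REPTOR, a transcription factor controlled by the TOR pathway, 1.21 ± 0.12 (0.0535); the anion exchanger gene Ae2, 1.51 ± 0.17 (0.1391); and CG42613, 1.06 ± 0.13, the RNA methylation reader gene Ythdf, 1.60 ± 0.21, and CG7695, 1.11 ± 0.15 (each 0.2120).

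**Figure D3:**
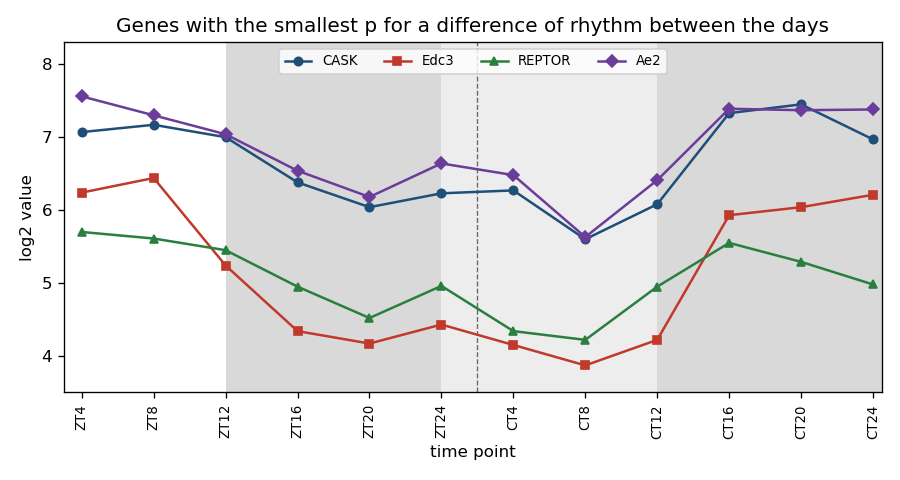
Log2 values of CASK, Edc3, REPTOR and Ae2 at the 12 time points, 1 point per array. Grey marks darkness and light grey the subjective day, and the dashed line separates the light/dark from the constant darkness arrays. CASK lies at 7.17 in ZT8, 5.60 in CT8 and 7.45 in CT20.

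In limma, 278 genes had an unadjusted p under 0.05 for this difference, against 542 by chance. The low stretch of CASK includes CT8, the array with high gut and low neuron markers, and all 3 arrays with a large 3' minus 5' signal, ZT16, ZT24 and CT4 (CASK at 6.38, 6.23 and 6.27). Without these 4 arrays the size for CASK was 1.65 and the call was lost (adjusted p = 0.9199), with only 8 arrays left behind the spread. The CASK call was lost when any of 9 arrays was left out, with adjusted p of 0.1046 without ZT4, 0.1693 without ZT8, 0.1722 without ZT12, 0.1520 without ZT16, 0.1092 without ZT20, 0.2884 without CT8, 0.1023 without CT12, 0.0838 without CT20 and 0.0733 without CT24; without ZT24 the call was joined by Edc3 (0.0443) and Ythdf (0.0455) among the named genes. The size for CASK stayed between 1.49 and 1.63.

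Mean levels of single genes were not shown to differ between the days. Among the genes with the smallest p, the iron carrier gene Tsf1 measured 9.32 ± 0.30 (SD, n = 6) in constant darkness and 8.83 ± 0.21 in light/dark, a difference of 0.49 ± 0.12 (SE), and Drsl5, a relative of the antifungal peptide drosomycin, differed by 0.86 ± 0.21. Differences were 0.42 ± 0.10 for the proline synthesis gene P5CS, 0.28 ± 0.06 for the dolichol kinase gene Dolk and 0.58 ± 0.15 for SmydA-8. Lower values in constant darkness were those of CG3770 (-0.28 ± 0.06), the chitin-binding protein gene Gasp (-0.41 ± 0.10), CG10512 (-0.34 ± 0.08), the fat body protein gene Fbp2 (-0.37 ± 0.10) and the signal peptide peptidase relative SppL (-0.19 ± 0.05). In limma 0 genes passed (smallest adjusted p = 0.9298), and 417 had an unadjusted p under 0.05, against 542 by chance. Of the 417, 187 were higher and 230 lower in constant darkness. Adjusted over the list alone, Drsl5 passed in the immune list (adjusted p = 0.0283). Of that list's 16 genes 6 were higher and 10 lower, with Dif, an NF-kappaB factor, at -0.35 ± 0.14. In the head fat body list Tsf1 and Fbp2 passed, in opposite directions (smallest adjusted p = 0.0213), and 8 genes were higher and 8 lower. These values were not adjusted over the 28 lists searched, so such passes can arise by chance. For tim the difference was -0.43 ± 0.19.

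As groups, ribosomal protein and oxidative phosphorylation genes were called higher in constant darkness by camera with its preset correlation. With an estimated correlation or with fry they were not called. Of 38 ribosomal protein genes 34 were higher, with a median difference of 0.20, such as RpL23 (0.33 ± 0.17) and RpL32 (0.20 ± 0.10); camera gave an adjusted p of 2.484e-07, and adjusted p = 0.4500 with an estimated correlation. Of 73 genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, 57 were higher, with a median of 0.17, such as ND-75 (0.51 ± 0.20) and COX5A (0.35 ± 0.18); camera gave 1.227e-06, and adjusted p = 0.4500 with an estimated correlation. Quantile normalization again brought these medians to 0.06 (camera adjusted p = 0.0434) and 0.03 (0.2965, no longer a call). The ribosomal list's median was -0.44 in ZT16, and that of oxidative phosphorylation -0.33, in an array with a large 3' minus 5' signal and low muscle markers, and both were highest in CT8, at 0.32 and 0.31.

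Of the 3 lists of detoxification enzymes, 2 were called higher in constant darkness as groups by camera with its preset correlation. Of 81 cytochrome P450 genes 55 were higher (median 0.06; Cyp6a22 0.20 ± 0.07, Cyp6d5 0.57 ± 0.24), and of 34 glutathione S-transferase genes 25 (median 0.11; GstE12 0.42 ± 0.19, GstE9 0.44 ± 0.25). Camera gave an adjusted p of 0.0023 for each, and adjusted p = 0.4500 for each with an estimated correlation. The P450 call was lost without ZT20 (adjusted p = 0.0549; median 0.09 without CT16), and the glutathione S-transferase call without ZT20 (0.0502) or CT12 (0.0692; median 0.065). Of 33 UDP-glycosyltransferase genes, 19 were higher and 14 lower, with a median of 0.01 (camera adjusted p = 0.5299).

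Of 25 phototransduction and photoreceptor genes, 18 were higher in constant darkness, with a median of 0.12. Examples are the retinophilin gene rtp (0.48 ± 0.15), the eye protein kinase C gene inaC (0.34 ± 0.16) and the lens protein gene retinin (0.19 ± 0.08). Camera gave an adjusted p of 0.0142, and adjusted p = 0.5990 with an estimated correlation. The call was lost without ZT12 (0.0723), ZT16 (0.1657), ZT20 (0.0502) or CT12 (0.5166; median 0.07), and with quantile normalization again (median 0.05, adjusted p = 0.3408); the median was 0.213 without CT4, 0.185 without ZT8 and 0.188 without ZT24. The list's median was lowest in ZT16, at -0.32, where the 3' minus 5' signal was large. Of 33 feeding and lipid genes 23 were higher (median 0.07; malic enzyme gene Men 0.29 ± 0.12, fatty acid desaturase gene Desat1 0.31 ± 0.14, against -0.21 ± 0.10 for the lipase gene bmm). Camera gave an adjusted p of 0.0324, and adjusted p = 0.5017 with an estimated correlation. This call was lost without ZT4 (0.1067), ZT12 (0.0870), ZT16 (0.1835), ZT20 (0.1389), CT12 (0.5166), CT16 (0.0687) or CT24 (0.0997), and with quantile normalization again (median 0.02, adjusted p = 0.4473). The feeding and lipid list's median, too, was lowest in ZT16, at -0.17.

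Receptors for smell and taste, which are weakly expressed in whole heads, went the other way. Of 124 odorant and gustatory receptor genes 103 were lower in constant darkness, with a median of -0.06, such as Gr98a (-0.31 ± 0.10, at a mean level of 3.76) and Or69a (-0.27 ± 0.10, at 3.59). Camera gave an adjusted p of 6.491e-06, and adjusted p = 0.6795 with an estimated correlation. The median was -0.03 with 16 added on the linear scale, and -0.04 with quantile normalization again or without CT12 (camera adjusted p = 9.421e-06, 0.0036 and 0.0114). The list's median was 0.12 in ZT12 and ZT16 and 0.09 in CT4, arrays in which muscle markers were low. None of the 7 called lists passed with an estimated correlation or with fry (adjusted p of 0.6683 to 0.7089), which tests whether a list's genes move on balance 1 way.

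Of the other 21 lists, none passed in camera with all arrays. Adjusted p was 0.0933 for the earlier reported head oscillators, 0.1690 for cuticle proteins, for haemocyte markers and for testis and accessory gland markers, and 0.3748 for ovary markers. It was 0.4622 for the core clock, for eye pigment and pteridine genes and for neuropeptides and receptors, and 0.5110 for the proteasome, odorant-binding proteins and head fat body markers. The value was 0.5299 for UDP-glycosyltransferases, immune effectors and muscle markers, 0.5560 for glia, and 0.6139 for activity-regulated genes, ion channels and neuron markers. It was 0.6542 for gut markers, 0.7017 for clock kinases and modifiers, and 0.8014 for heat shock and stress. Without CT8, 6 of these lists passed: gut (4.789e-04), testis and accessory gland (0.0033) and ovary markers (0.0192) and cuticle proteins (0.0083) as lower, and head oscillators (0.0411) and haemocyte markers (0.0486) as higher in constant darkness. With an estimated correlation their adjusted p without CT8 lay between 0.2813 and 0.5273. With any other array left out, 0 to 3 of the 21 passed. Without ZT16, ZT24, CT4 and CT8, 8 passed: these 6, immune effectors (6.162e-04) and head fat body markers (0.0487), the last 2 as higher. With an estimated correlation these 8 had adjusted p between 0.2412 and 0.4603 in that fit. Its days no longer hold the same hours, so a difference between the days is partly confounded with the hour there. The proteasome passed as lower with the 3' minus 5' signal as a covariate (3.312e-04), and not with an estimated correlation (adjusted p = 0.6517). With an estimated correlation and all arrays, adjusted p of all 28 lists lay between 0.4500 and 0.8725. Per gene, limma called 0 members of any list over all genes, as no gene passed.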

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

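The tests weighed here were chosen after the results were seen, although the fit without CT8 was itself among the alternatives fixed in advance; the list of marker genes for body tissue was written before the data were examined, and of its genes Jon25Biii, Mst57Da and Acp95EF were chosen after their values were seen.

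In several measures, some of them part of the patterns weighed below, 1 array stood far from the other 5 of its day, by a gap divided by the range of at least 0.71. Muscle markers in CT4 had a median of -0.29, against 0.08 to 0.14 in the other constant darkness arrays (gap 0.86). The blue-light receptor gene cry was at 6.63 in CT4, against 7.66 to 7.91 (gap 0.80), and was also low in ZT16 and ZT24 (6.74 and 6.82), the other arrays with a large 3' minus 5' signal, and the clock gene cyc was at 5.48 in ZT8, against 5.83 to 5.92 (gap 0.80). Neuron markers in CT8 had a median of -0.49, against -0.01 to 0.19 (gap 0.71), and glia markers -0.13, against -0.01 to 0.04 (gap 0.71). Of 50 such groups 5 stood out, and chance alone picks about 1 in 20 groups. CASK was picked out because its daily rhythm differed between the days (adjusted p = 0.0255).

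On the first principal component, which held 44.6% of the variance, ZT12, ZT16, ZT24 and CT4 stood apart from the other arrays. A daily rhythm shared by both days is argued against, since 70.0% of the 720 pairings of light/dark with constant darkness arrays lay at least as close on this component as the same-hour pairs (mean distance 23.3, median over pairings 21.3). Partly degraded RNA or shortened cDNA stays open: the 3' minus 5' signal followed the component with r = 0.85 (permutation p = 4.000e-04, adjusted 4.000e-04) and rho = 0.71 (permutation p = 0.0130, adjusted 0.0130), r = 0.82 without ZT24 and CT4, and 0.84 and 0.88 within the days. Less cRNA on these arrays stays open too, since the mean of the spike-in controls followed it with r = 0.87 (permutation p = 2.000e-04, adjusted 4.000e-04) and rho = 0.86 (permutation p = 7.100e-04, adjusted 0.0014), r = 0.91 without CT8 and ZT12, and 0.89 and 0.81 within the days. These 2 relations were the ones computed, over 12 arrays, and each leaves 1 array aside: ZT12 lies far out with a 3' minus 5' signal of only 2.13, and CT16, at a score of 3.6, had a spike-in mean of 10.15, close to the 10.13 of CT4, at 24.2.

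In CT8, gut genes were high and neuron genes low. A shift of weakly expressed probe sets is argued against, as the gut list's median difference of 0.31 lay at the percentile 100.0 of 10000 random lists of matched level, and so is a daily rhythm shared by both days, as the same list in ZT8 was at -0.08. The gut list had been picked for its height in CT8, and its genes vary together (estimated correlation 0.394), which random lists do not copy. The percentile therefore overstates the contrast. Body tissue mixed with the heads stays open. Of the 30 gut genes, 16 had their highest value in CT8, among them Jon25Biii (5.84 against 3.92 ± 0.13, SD, n = 11), LysE (8.74 against 7.73) and LysD (8.36 against 7.10). This count restates the pattern and cannot favour 1 cause over another. Of the 26 testis and accessory gland genes, 8 were highest in CT8, with a list median difference of 0.06. The accessory gland genes Mst57Da (7.48 against 5.12) and Acp95EF (6.10 against 4.51) differed most in that list, which pools testis with accessory gland genes. Of the 20 ovary genes, 7 were highest and 1 was lowest in CT8, with a list median difference of 0.17. Against a simple mixture of whole bodies, the gut gene LysS was at 8.29 against 8.74, the testis genes Mst84Dd and Mst87F at 7.19 and 6.08 against 7.19 and 6.21, and 9 of the 16 neuron genes were lowest, with a median of -0.54, more than a small added share could dilute. Of the marker genes, none of the gut list stands in another list, heads were separated by sieving, and no biological cause particular to CT8 was tested.

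CASK was high at ZT4 to ZT12 and at CT16 to CT24 and low between, and was weighed with the 6 genes next in p, not all of which had this course (CG7695 was at 6.40 in ZT12 and 6.67 in CT12). Degraded RNA is argued against only weakly: with the 3' minus 5' signal as a covariate, the median size of the difference of these 7 genes was 102.0% of that without. The genes had been picked for this difference in the same data, which favours a size that lasts here and without CT8. The low stretch of CASK also holds all 3 arrays with a large 3' minus 5' signal. Body tissue in CT8 is argued against as the whole cause, since without that array the size was 94.7% of that with it, although the CASK call itself was then lost (adjusted p = 0.2884) at a size of 1.51 against 1.56 ± 0.12, with 1 array fewer behind the spread. A single slow wave in place of daily rhythms cannot be told apart from them here: a 36-hour cosine predicted left-out arrays better for 1 of the 7 genes, but these genes had been picked for separate rhythms, which favours that model. A response to the loss of light also stays open and untested, as the design holds 1 cycle of each lighting.

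Chance could not be excluded for any count of genes. Each set of regroupings below, and each count of matches, includes the real arrangement itself. At least as many genes as the real 1 rhythmic gene were called in 7 of 100 permutations of the hours within days, and another permutation gave 468. The 379 genes at an unadjusted p under 0.05 in the light/dark day were matched by 21 of 60 orders of its arrays (highest other 1134), and the 172 in constant darkness by 44 of 60 (highest other 1214). For the 1 gene with a difference of rhythm, 2 of 32 exchanges of days within hours gave as many, with at most 2 in any other. The 417 genes for the mean level were matched by 44 of 100 splits drawn from 462 (highest other 3601), and another split called 1507 genes past the threshold. Splits that call so many genes point to a structure of the arrays other than hour and day.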

How the results depend on the processing

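Chosen after the results were seen were the fits with covariates, principal components, array weights, a squared time term or without several arrays at once, the permutation test of lists, and the reruns of lists for the mean level without single arrays or under other normalizations.

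The count of 1 gene for the 24-hour rhythm over both days was the same with weak probe sets left out, centring, another variance prior, all probe sets, the hour as a factor, a 12-hour term, no day term, the 3' to 5' signal as a covariate and the first component. It was 0 with quantile normalization again, with 16 added on the linear scale, with elapsed hours in place of the day step, with array weights and with squared elapsed hours, where vri had adjusted p of 0.0742, 0.1129, 0.0722, 0.0721 and 0.1318 at amplitudes of 0.72, 0.57, 0.71, 0.67 and 0.71. It was 7 without ZT16, ZT24, CT4 and CT8 and 2 with the first 2 components as covariates, and 0 to 1 with 1 array left out. The light/dark day stayed at 0 genes in all planned fits, and had 2 with the 3' to 5' signal, 3 with that and the gut list, 2 with the first component and 0 with the first 2 components as covariates. Constant darkness stayed at 0 genes in all planned fits, and had 1 with the first component and 1 with the first 2. The count for the difference of the 24-hour rhythm between the days, 1, became 2 with quantile normalization, 3 with another variance prior, 5 with the 3' to 5' signal, 13 with the first component, 25 with the first 2, 0 without the 4 arrays, and 0 to 4 with 1 array left out. The count for the mean level, 0, stayed 0 in planned fits other than that without CT4 (0 to 1 with 1 array left out) and was 9 without the 4 arrays, where the days hold unlike hours. Of the gene lists for the rhythm, 1 was called by Fisher's exact test and 0 by permutation of the hours, where 100 orders were too few for 1 list alone to pass. Of those for the mean level, 7 were called by camera, 0 with an estimated correlation, 0 by fry, 15 without the 4 arrays, 13 without CT8, and 0 with an estimated correlation without the 4 arrays, without CT8 or with the 3' to 5' signal as a covariate; with 1 array left out the count was 3 (without ZT20) to 13. The share of the vri amplitude kept in constant darkness, 1.0 for a gene picked by a common rhythm, was 0.952 with quantile normalization. It was 0.838 to 1.18 with 1 array left out. Where an array is left out, fewer arrays stand behind the spread; the cause of the other changes was not tested.

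Hours of both days share replicate numbers, which mark the hour and not the same flies. Over the 6 same-hour pairs, correlations of deviations from the day's mean ran from -0.64 to 0.39, 2 were over 0.1, and 0 of the 12 arrays were closest to the array of their own hour. With the hour as a replicate block, limma gave 0 genes for the mean level and 7 lists, so this block changed no call.

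Some small values changed sign, none of them a call. The rhythm of cry, measured along its fitted phase, was -0.005 without ZT24 (-0.005 to 0.161 with 1 array left out), -0.011 with the 3' to 5' signal as a covariate (-0.011 also without weak probe sets, -0.016 with no day term), -0.026 with the gut list added, -0.019 with array weights and -0.044 without the 4 arrays. CG8910 was at -0.006 with the first 3 components. Without the 4 arrays, the rhythm components were -0.002 for Calx, -0.025 for Ih, -0.004 for LysB and -0.007 for LysD, and the differences between the days 0.061 for vri, 0.026 for Fbxl4, -0.082 for Arc1, -0.034 for stv, 0.076 for Syn, 0.021 for bt, -0.112 for Mlp84B and -0.052 for Cp19. The difference for CG6770 was -0.011 without CT12 (-0.011 to 0.473 with 1 array left out). Of the values for single named genes, 3300 for the rhythm, 126 for the difference and 2859 for the mean level kept direction and side of the threshold, as did 88 for the called lists. Most of these genes were never called, so keeping their side was nearly certain and says little about the calls of vri and CASK. Calls were lost 15 times for the rhythm, all of vri, and 10 times for the difference, all of CASK. For the mean level 0 were lost, and for the called lists 17. Calls gained were 1, 18, 1 and 0 in the same order. Genes near the floor, such as most smell and taste receptors, are limited by signal over background, which RMA values do not show.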

Other observations

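The genes, fits and groupings of this part were picked out only after the values had been seen.

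The genes ple and t passed for the light/dark rhythm with the 3' minus 5' signal as a covariate. The gene ple encodes tyrosine hydroxylase, the first enzyme of dopamine synthesis, and t encodes tan, which splits the conjugates that recycle histamine at photoreceptor synapses. The transcript of ple was at 8.80 in ZT4, 7.17 in ZT12 and 6.99 in ZT16, and between 7.20 and 7.89 throughout constant darkness. From ZT4 to ZT24, t was at 7.58, 6.61, 5.68, 5.77, 7.95 and 6.66. Its fitted peak with the covariate lay at 23.9 hours, although ZT24, the array with the largest 3' minus 5' signal (3.32), was below ZT20. With the 3' minus 5' signal as a covariate, limma called the light/dark rhythm of ple (amplitude 0.85, adjusted p = 0.0065) and t (1.13, adjusted p = 0.0465), against adjusted p of 0.8298 and 0.9939 without it. With the first 2 components as covariates, 0 genes were called for the light/dark day. The low points lie in ZT12 and ZT16, which also stand apart on the first component.

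Without ZT16, ZT24, CT4 and CT8, limma called a rhythm over both days in GstE6, Mppe, Mtk, vri, Obp57c, PIP4K and CG16978 (adjusted p = 0.0407 each) and a mean level that differed between the days in GstE6, Mppe, PIP4K and 6 other genes. Among the 8 remaining arrays these genes other than vri were lowest in ZT20: Mppe was at 5.32 there, against 6.11 to 7.65 in the other 7, and GstE6 at 4.78, against 5.54 to 6.63. Dependence of these calls on ZT20 was not tested. The days of this fit hold unlike hours (ZT4, ZT8, ZT12 and ZT20 against CT12, CT16, CT20 and CT24). Its day and rhythm terms are thus partly confounded, and neither set of calls can be read alone. The antimicrobial peptide gene Mtk was at 6.99 in ZT20, against 7.75 to 9.04 in the other remaining arrays.

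The control probe set for the middle of 18S ribosomal RNA was at 7.23 in ZT4, 6.85 in ZT8, 6.83 in ZT12 and 6.31 in CT12, and between 4.40 and 5.25 in the other 8 arrays. These 4 arrays were collected in the light or in the subjective day up to its end, but CT4 and CT8, at 4.99 and 5.21, were not among them.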
